A study of Microhyla fissipes with 11 samples.

How the data were processed

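RNA was measured in whole tadpoles of the ornamented pygmy frog Microhyla fissipes at developmental stage 29. Per the labels, embryos were reared for 10 days on a white or a black background, in water with corticosterone at 0 or 1 µmol/L. Corticosterone is the main glucocorticoid of amphibians. The 11 libraries fall into 4 groups by their labels: 3 unexposed on black (control_black), 3 unexposed on white (control_white), 3 exposed on black (CORT_black) and 2 exposed on white (CORT_white). The labels do not say whether a library is a single tadpole or a pool, or whether the libraries of a group came from separate containers, so every p-value measures the spread between these libraries, which may be partly technical. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was taken up on poly-T beads, and paired-end reads were sequenced on an Illumina HiSeq instrument.

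The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) as deposited by the authors, in a single file of assembled genes with identifiers in the form that the Trinity assembler gives and with columns of protein database hits. The aligner and the counter are not given in the sources used here. The table had 222820 lines for 218206 assembled genes. Of these genes, 4062 stood on several lines, 0 of them with differing FPKM, and 1 line per gene was kept. A gene took a name from its Swiss-Prot BLASTX hit when the hit was a chordate protein with an E-value of 1e-10 or less, which named 26594 genes. The symbol of an entry came from a table written by hand, else from the symbol most often given by the nucleotide database hits of the genes with that entry, else from the entry's own name, so a symbol can stand for a relative of the protein hit. In the table written by hand, 1 wrong symbol, of an amino acid transporter, was corrected after the data were seen. Several assembled genes can carry 1 name, because an assembly without a genome can split a gene or hold paralogs apart. Values of such families, trypsins and elastases among them, are therefore uncertain as to which copy they belong to.

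FPKM are not counts, so the fits used log2(FPKM + 1), and every fold change is on that scale, which understates the change of genes with low values. Assembled genes with an FPKM of 1 or more in at least 2 samples were tested: 80014 genes, of which 17779 (22.2%) had a name, under 12790 distinct symbols, and 60090 had no Swiss-Prot hit. A 4-group means model was fitted to all 11 samples together with limma 3.58.1 in R 4.3.3 (moderated test with a mean trend), with no replicate block, so that the group of 2 libraries shared the estimate of the spread. The contrasts were corticosterone on black, corticosterone on white, white against black without and with corticosterone, the averages of both pairs, and the interaction. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. FPKM were not rescaled between samples.

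Gene lists covering hormones, pigment cells, metabolism, immunity and marker genes of tissues were written before the data were examined, as were the samples, the contrasts, the tests, most alternatives and the rule for named genes. There were 40 lists with 1076 symbols, of which 39 had at least 5 measured members. They were tested with camera in limma, with a preset correlation of 0.01 between genes and with adjustment over the lists of a comparison. Camera compares the moderated test statistics of a list with those of the other named symbols. Its direction is therefore relative to them and can differ from the sign of a list's median or mean. Over all named symbols the median log2 change with corticosterone was 0.22 on black and 0.14 on white. The assembled gene with the highest mean stood for a symbol. For list members, calls over all genes tested are given beside calls adjusted over the list alone. Camera with an estimated correlation called 0 lists in each of the 7 comparisons, and its smallest adjusted p was 0.205, so each call of a list rests on the preset correlation. With the preset correlation, 16 of the 39 lists were called on black, 16 on white and 13 in the average corticosterone contrast. Between backgrounds it called 20 lists without corticosterone, 17 with it and 13 on average, and 19 for the interaction. Those 4 contrasts called only 29, 3, 8 and 12 single genes. With fry, which asks whether the genes of a list move on balance one way, 10 lists were called on black, 3 on white and 14 in the average corticosterone contrast. Fry called 0 lists in each background contrast and for the interaction.

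The named genes follow 3 rules. In each comparison they are the 6 largest rises and the 6 largest falls among called, named genes whose libraries do not overlap between the groups, then up to 4 called members of each list by smallest adjusted p, and last a fixed set of genes known for glucocorticoid response or pigmentation, called or not. A gene that stands outside these rules is marked as chosen after its values were seen. No rule set which of the lists are described.

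Depth could be compared between samples because FPKM of a low gene are multiples of the value of a single fragment. Among genes under 0.3 FPKM, between 90.9% and 92.5% had ratios between libraries that matched ratios of whole numbers up to 5 within 0.01 on the natural log scale. The depth of the 11 libraries relative to control_black_1 lay between 0.965 and 1.03, so the libraries differed little in depth. The absolute number of fragments is unknown, and no counting interval is given.

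The fits were tested on simulated data before use, with 200 genes changed, 100 for each size of change. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1. The noise was normal, independent between genes and of the same spread in each library. The shares recovered need not hold for lower genes or where a library stands apart. Nor need they hold where far more genes change, since the adjustment then sets a looser cutoff on the unadjusted p. For corticosterone on black, 26% of changes of 1 on the log2 scale and 79% of changes of 2 were recovered over 74308 genes, with 8 false calls. For corticosterone on white these shares were 12% and 61% over 74287 genes, with 2 false calls. For white against black without corticosterone they were 26% and 77% over 74226 genes, with 4 false calls.

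Alternatives changed 1 choice at a time: the pseudocount, the filter on low values, rescaling to an equal sum per library (TPM), median-of-ratios scaling, quantile normalization, a replicate block, robust moderation, sample weights, fits of the 2 groups alone, a minimum fold change, and each library left out. Restricting the test to genes with a chordate hit, and testing the lists with each library left out, were added after the data were seen. Table preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The prepared table was read into R with data.table (version 1.17.8), and all splits and label permutations were run in R. No genome was used, so gene positions are not given.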

Results

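Whole-tadpole RNA from the 4 groups gave FPKM for 161369 to 178146 assembled genes above 0 per library. The sum of FPKM per library lay between 1048800 and 1192655, and the 100 highest genes held 29.8% to 37.7% of it. Pearson correlations of log2(FPKM + 1) between pairs of libraries, across genes, which are not independent replicates, ran from 0.850 to 0.962. The first principal component took 33.4% of the variance and separated the exposed libraries (scores 55.6 to 88.7) from the unexposed ones (−90.1 to −34.2). The second took 20.2% and set control_white_1 (−158) apart from the other libraries (−14.3 to 49.7). In control_white_1 the lens gene CRYAA stood at 0.753 FPKM against 7.03 to 69.3 elsewhere, and the gene of the pancreatic protease precursor chymotrypsinogen, CTRB1, at 14301 against 254 and 38.2 in the other control_white libraries. These genes were chosen after their values were seen. This library lies in the unexposed white group, so it enters each contrast of that group. All contrasts take the spread from 1 fit, so it also bears on the calls of the other contrasts. Without control_white_1 the calls for corticosterone on black went from 7662 to 11649, while the median log2 change went from 0.059 to 0.062.

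**Figure D1:**
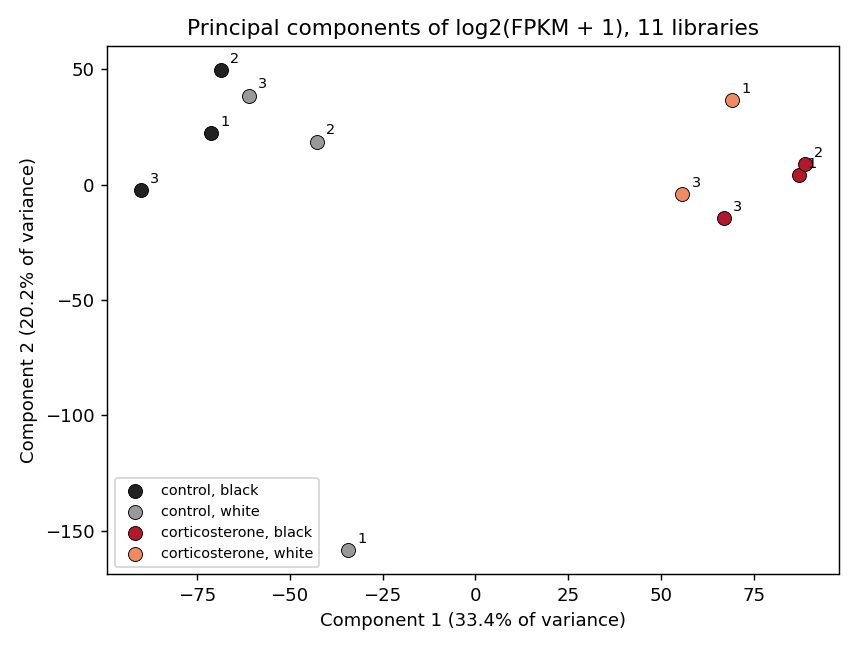
Scores of the 11 libraries on the first principal component (33.4% of the variance, x axis) and the second (20.2%, y axis) of log2(FPKM + 1), coloured by group. The 5 exposed libraries lie at 55.6 or more on the first axis, and control_white_1 lies alone at −158 on the second.

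The first comparison asked what 10 days of corticosterone did to tadpoles on a black background. Genes known as direct glucocorticoid targets rose: the transcription factor gene KLF9 (TRINITY_DN40731_c5_g1) went from 0.530 ± 0.161 to 9.02 ± 1.22 FPKM (SD, n = 3 and 3), a log2 change of 2.71 ± 0.28 (SE, adjusted p = 2.1e-04; 4.11 with a pseudocount of 0.01), and DDIT4, an inhibitor of growth signalling through mTOR, from 10.7 ± 1.58 to 57.8 ± 15.9 FPKM (2.30 ± 0.20, adjusted p = 7.8e-05). The ammonium transporter gene RHCG rose from 7.08 ± 4.0 to 127 ± 15.3 FPKM (4.11 ± 0.40, adjusted p = 1.7e-04). Of 35 contractile genes of skeletal muscle 23 fell, with titin (TTN) going from 848 ± 159 to 296 ± 36.2 FPKM (−1.51 ± 0.18, adjusted p = 5.7e-04). Of 80014 genes tested, 7662 were called, 4887 higher and 2775 lower with corticosterone, and among 1862 called symbols 1592 rose and 270 fell. The rises made up 63.8% of the calls, against 75.03% after rescaling to TPM, 49.0% with median-of-ratios scaling and 52.1% with quantile normalization. The median log2 change over all genes tested was 0.06, against 0.14, −0.02 and −0.0027 with these scalings in turn. The count of calls was 2829 without CORT_black_2, 3034 without CORT_black_1, 4705 without CORT_black_3, 3936 without control_black_3 and 11649 without control_white_1.

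The largest rises on black included genes of pancreatic proteases. Trypsin-3 (PRSS3) went from 1.19 ± 0.580 to 451 ± 158 FPKM (7.65 ± 1.09, adjusted p = 0.0017), and an assembled gene of cationic trypsin (PRSS1, TRINITY_DN45301_c3_g2) from 1.80 ± 0.511 to 951 ± 291 FPKM. An elastase gene (CELA1, TRINITY_DN46020_c2_g4) rose by 7.87 ± 1.48. The unexposed library control_white_1 held this PRSS1 gene at 1357 and this CELA1 gene at 1316 FPKM, above each CORT_black library (614 to 1120 and 398 to 838). The largest rise among named genes whose libraries did not overlap was that of carbonic anhydrase 1 (CAH1, TRINITY_DN37194_c6_g1), which hydrates carbon dioxide, by 8.44 ± 0.96, from 0.116 ± 0.125 to 403 ± 137 FPKM. The list of digestive genes of pancreas and gut had 26 measured members. Of these, 5 are not enzymes: VIL1, FABP2, the granule proteins GP2 and SYCN, and colipase (CLPS), a cofactor of lipase. Of the 26, 13 rose and 6 fell (14 and 7 adjusted over the list alone). The list median was 2.82, yet camera gave a downward direction with an adjusted p of 0.859, so the sign of its median and of its test differ and the list was not called. Intestinal genes that are not enzymes were among those that fell: villin (VIL1), which builds the brush border, by −1.22 ± 0.19, and the fatty acid binding protein of the enterocyte (FABP2) from 2200 ± 836 to 777 ± 121 FPKM. The largest falls among named genes whose libraries did not overlap were in uromodulin (UROM, TRINITY_DN51310_c4_g1), from 154 ± 95.2 to 0.950 ± 0.216 FPKM, in VMO1, from 137 ± 89.8 to 2.24 ± 1.69 FPKM, and in an assembled gene of the mucin MUC5AC (TRINITY_DN50603_c2_g4), from 161 ± 59.7 to 3.48 ± 1.49 FPKM (−5.15 ± 1.48, adjusted p = 0.0498). The MUC5AC call ended without any one of control_black_1 to control_black_3 (adjusted p = 0.0995 to 0.11), CORT_black_1 to CORT_black_3 (0.094 to 0.15), CORT_white_1 (0.066) or CORT_white_3 (0.067), with a range of 1.6e-05 to 0.15 over all alternatives. Next were another assembled gene of UROM (TRINITY_DN50901_c7_g1; −4.26 ± 0.59), the secreted mucin MUC2, from 174 ± 81.9 to 8.06 ± 3.03 FPKM, and the amino acid transporter SLC6A14 (TRINITY_DN43430_c7_g3), from 108 ± 16.4 to 5.09 ± 0.901 FPKM (−4.16 ± 0.25, adjusted p = 7.6e-06).

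Of 23 measured genes in the list of glucocorticoid-induced genes, 15 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 change of 1.04 (camera adjusted p = 1.1e-05; adjusted p = 0.232 with an estimated correlation). CEBPB, a transcription factor of the acute response, rose by 1.92 ± 0.23 and ZBTB16, a repressor of transcription, by 1.17 ± 0.20 (4.12 with a pseudocount of 0.01). TSC22D3, the anti-inflammatory GILZ gene, changed by 0.58 ± 0.17 (adjusted p = 0.052; 0.029 without control_black_3 and 0.025 without control_white_1, with a range of 0.0063 to 0.17 over all alternatives), the glucocorticoid receptor NR3C1 by 0.28 ± 0.15 (adjusted p = 0.29) and the gluconeogenic PCK1 by 0.38 ± 0.40 (adjusted p = 0.61), and none of these passed the test. FKBP5 and DIO3 were not measured. Amino acid catabolism and the urea cycle had 8 rises and 0 falls among 26 genes (14 and 0 adjusted over the list alone; median 1.01, adjusted p = 0.0046; adjusted p = 0.934 with an estimated correlation). Among them tyrosine aminotransferase (TAT) went from 4.43 ± 0.720 to 38.4 ± 6.21 FPKM and proline dehydrogenase (PRODH) rose by 1.82 ± 0.20. The enzyme AKR1D1, which reduces the steroid A ring, went from 31.6 ± 5.45 to 485 ± 73.1 FPKM (3.90 ± 0.25, adjusted p = 9.5e-06). In the circadian clock list PER1 rose by 1.19 ± 0.21 and NFIL3 by 0.94 ± 0.14; 4 of 17 members rose and 0 fell (5 and 0 adjusted over the list alone).

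Skeletal muscle contractile genes had 23 falls and 1 rise among 35 measured members (the same counts adjusted over the list alone), with a median of −1.11 (adjusted p = 4.6e-22; adjusted p = 0.205 with an estimated correlation). The myosin heavy chain MYH8 went from 3686 ± 747 to 1080 ± 258 FPKM, the fast troponin TNNI2 fell by −1.41 ± 0.20 and ACTN3, the actinin of fast fibres, by −1.25 ± 0.17. Ion transport and gill genes rose in 12 of 20 cases with 0 falls (13 and 0 adjusted over the list alone; median 1.04, adjusted p = 3.2e-04; adjusted p = 0.934 with an estimated correlation). These held SCNN1B, a subunit of the epithelial sodium channel (2.01 ± 0.23), and 2 subunits of the proton pump, ATP6V1B1 (1.96 ± 0.21) and ATP6V0D2 (1.44 ± 0.18). Matrix metalloproteinases and their inhibitors TIMP1 and TIMP3, both called, had 6 rises and 0 falls among 13 (9 and 0 adjusted over the list alone; median 0.61, adjusted p = 0.0080; adjusted p = 0.934 with an estimated correlation), with stromelysin MMP3 going from 5.45 ± 0.837 to 33.1 ± 5.71 FPKM and gelatinase MMP2 up by 1.47 ± 0.18. The chains of type I collagen fell, COL1A2 from 1821 ± 226 to 432 ± 61.4 FPKM and COL1A1 from 826 ± 208 to 281 ± 30.8 FPKM, while in the whole collagen matrix list 3 of 22 genes rose and 3 fell, also adjusted over the list alone. That list was called downward relative to the other named symbols (camera adjusted p = 0.024, and 0.934 with an estimated correlation). Its median was 0.09 and its mean −0.06, against a median of 0.22 over all named symbols. The call ended without control_black_2 (adjusted p = 0.065) or CORT_black_3 (adjusted p = 0.063). The deiodinase DIO2, which makes active thyroid hormone, fell by −1.45 ± 0.25, and the thyroid hormone receptor THRB changed by 0.41 ± 0.18 (adjusted p = 0.17).

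Cell cycle and replication genes (37 measured) shifted as a list by a median of −0.20 (adjusted p = 1e-06; adjusted p = 0.934 with an estimated correlation), and 0 members passed in limma, over all genes or adjusted over the list alone. That median was −0.44 without control_black_2, −0.05 without control_black_3 and −0.09 without CORT_black_3. In the epidermal list 5 of 17 genes rose, among them the cross-linking enzyme TGM1 (1.67 ± 0.17) and the desmosome gene PKP1 (1.76 ± 0.21; 3.67 with a pseudocount of 0.01), and 1 fell, the keratin KRT75 (−1.17 ± 0.17), with 8 and 2 adjusted over the list alone. In the list of growth hormone and insulin signalling 8 of 21 genes rose and 1 fell (13 and 1 adjusted over the list alone; median 0.66, adjusted p = 0.024; adjusted p = 0.934 with an estimated correlation, and 0.051 without control_black_3). These included the growth hormone receptor GHR (1.60 ± 0.26), the binding proteins IGFBP2 (2.06 ± 0.34; 3.52 with a pseudocount of 0.01) and IGFBP5 (1.52 ± 0.20), and the kinase subunit PIK3R1 (1.31 ± 0.16).

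**Figure D2:**
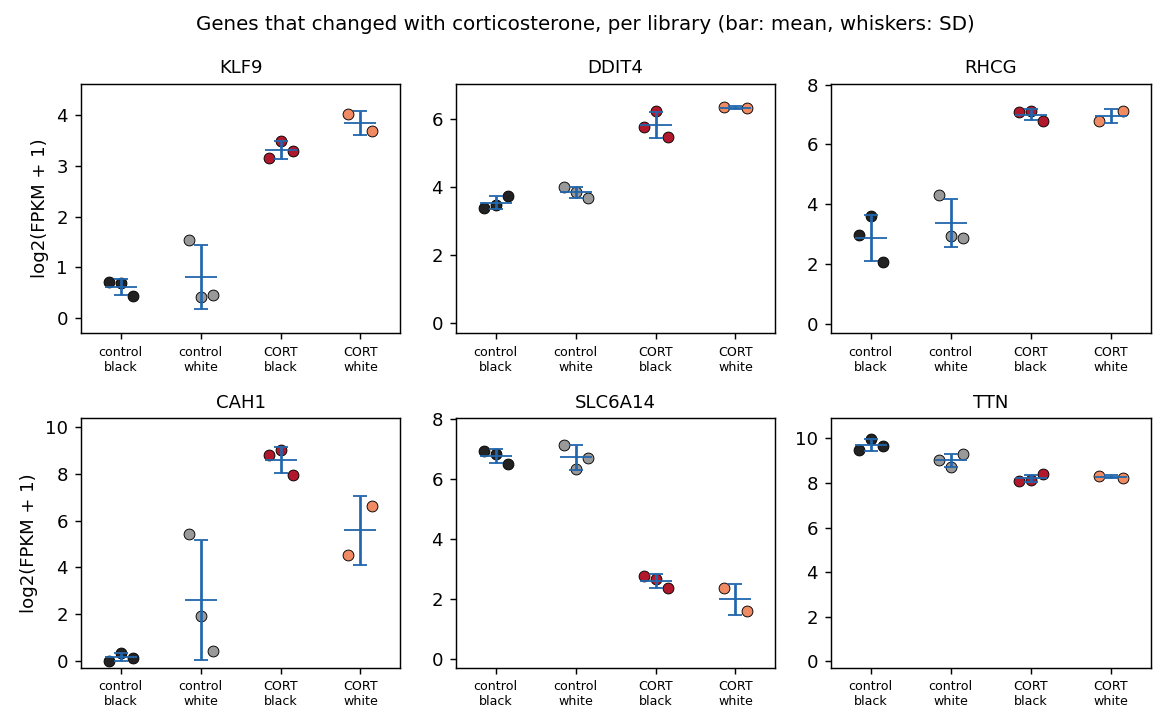
Values of log2(FPKM + 1) per library (points) for KLF9, DDIT4, RHCG, CAH1, SLC6A14 and TTN in the 4 groups, with the group mean (bar) and SD (whiskers; n = 3, 3, 3 and 2). KLF9, DDIT4 and RHCG are higher and SLC6A14 is lower in each exposed library than in each unexposed one, on both backgrounds.

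The second comparison asked the same on a white background, where 2 exposed libraries stood against 3. KLF9 rose by 3.05 ± 0.31 (adjusted p = 3.7e-04), from 0.872 ± 0.896 to 13.5 ± 2.38 FPKM (SD, n = 3 and 2), DDIT4 by 2.50 ± 0.22 (adjusted p = 1.5e-04) and RHCG by 3.57 ± 0.45 (adjusted p = 0.0016). The largest rise among named genes whose libraries did not overlap was in an assembled gene named for GP2, a glycoprotein of secretory granules (TRINITY_DN41119_c0_g1), from 0.362 ± 0.109 to 76.1 ± 2.48 FPKM (5.83 ± 0.21, adjusted p = 2.6e-07). Another assembled gene named for GP2 (TRINITY_DN47339_c1_g2) fell from 166 ± 67.9 to 22.7 ± 15.6 FPKM (−2.91 ± 0.48, adjusted p = 0.0089). That call ended without CORT_white_1 (adjusted p = 0.15) and when only the white libraries were fitted (0.17), with a range of 8.5e-04 to 0.17 over all alternatives. Next among the rises came cytochrome P450 2G1 (the protein hit of TRINITY_DN43279_c3_g1, which carries the symbol CYP2C14; 0.361 ± 0.0960 to 46.4 ± 6.50 FPKM) and AKR1D1 (19.8 ± 8.16 to 617 ± 95.9 FPKM), followed by the secreted glycoprotein OLFM4 (22.1 ± 12.7 to 553 ± 64.0 FPKM) and the melanosome regulator MREG (4.69 ± 0.37). SLC6A14 fell by −4.74 ± 0.28 and VMO1 by −5.81 ± 0.71. In all 1392 genes were called, 963 higher and 429 lower, and among 281 symbols 213 rose and 68 fell. The count was 429 without CORT_white_1, 530 without CORT_white_3, 847 without control_white_3 and 2153 without control_white_1; with 1 exposed library left, that library is assumed to vary like the other groups. Fitting the 5 white libraries alone gave 78 calls, which kept SLC6A14, AKR1D1, P450 2G1, the GP2 gene that rose, DDIT4 and PNP but not KLF9, RHCG, OLFM4, MREG or VMO1.

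Of the glucocorticoid-induced genes 12 of 23 rose on white and 0 fell (15 and 1 adjusted over the list alone; median 0.88, adjusted p = 5.6e-07; adjusted p = 0.263 with an estimated correlation). Glycogen synthase GYS1 rose by 1.51 ± 0.20 and glycogen phosphorylase PYGB by 2.03 ± 0.25. Of the genes named here, PNP alone was also called when the white libraries were fitted by themselves. The purine enzyme PNP went from 27.4 ± 0.589 to 149 ± 9.98 FPKM, and the sodium pump subunit ATP1B2 rose by 2.40 ± 0.30. NQO1, a quinone reductase of the antioxidant response, fell from 86.6 ± 7.55 to 17.2 ± 4.64 FPKM and KRT75 by −1.97 ± 0.19. In the collagen matrix list 2 of 22 genes fell and 0 rose (4 and 0 adjusted over the list alone; median −0.20, adjusted p = 1.1e-06; adjusted p = 0.820 with an estimated correlation), with a median of −0.02 without CORT_white_1 and −0.38 without CORT_white_3. Cell cycle genes had a median of −0.27 (adjusted p = 6.8e-09) and muscle genes of −0.33 (adjusted p = 9.8e-07), both with an adjusted p = 0.820 with an estimated correlation and with 0 members called by limma. The cell cycle median was 0.04 without CORT_white_1, where the test still gave a downward direction, and −0.58 without CORT_white_3. Of 26 digestive genes 1 rose and 3 fell (2 and 5 adjusted over the list alone; median −0.46, adjusted p = 1.9e-05; adjusted p = 0.820 with an estimated correlation). Without control_white_1, the library with CTRB1 at 14301 FPKM, this median was 0.59 and the call ended (adjusted p = 0.776), and it was −0.84 without control_white_2, −1.19 without control_white_3, −0.10 without CORT_white_1 and −0.88 without CORT_white_3. The member that rose was MEP1A, a call that ended without CORT_white_1 (adjusted p = 0.22; 0.0029 to 0.22 over all alternatives). Those that fell were GP2 (TRINITY_DN47339_c1_g2), MGAM and ANPEP. The MGAM call ended without CORT_white_3 (adjusted p = 0.063; 8.5e-04 to 0.17 over all alternatives). The ANPEP call ended without CORT_white_1 (adjusted p = 0.064) or CORT_white_3 (0.056; 0.0011 to 0.16 over all alternatives). Lens genes, crystallins for the most part, had a median of 3.04 (adjusted p = 2.8e-04; adjusted p = 0.821 with an estimated correlation), with 0 of 16 members called and 13 higher adjusted over the list alone; all 16 were lowest in control_white_1, and without it the median was 1.60.

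**Figure D3:**
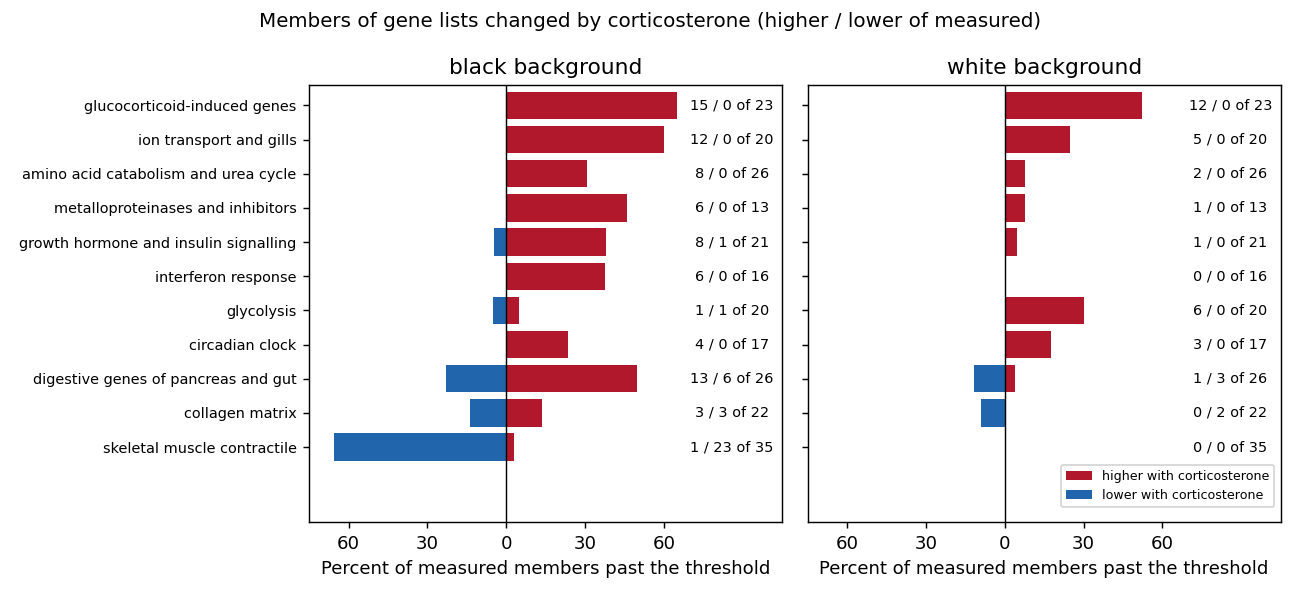
Percent of measured members (x axis) called higher or lower with corticosterone in 11 gene lists, on black (n = 3 against 3) and on white (n = 2 against 3), with counts beside the bars. The 11 lists shown were not picked by a rule. Glucocorticoid-induced genes have 15 of 23 members higher on black and 12 of 23 on white, and muscle contractile genes have 23 of 35 lower on black and 0 on white.

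The corticosterone effects on the 2 backgrounds share no library. Across the 80014 genes, which are not independent replicates, their log2 changes had a Pearson r of 0.549, with 0.436 without control_white_3 and 0.603 without control_white_1. Of the genes called on black, 90.4% changed in the same direction on white, with a median ratio of white to black of 0.495. These genes were picked by their call on black, which lowers the ratio even where effects are equal. It therefore does not measure how much weaker the response on white was. Genes called higher on both numbered 763 against 58.8 for independent lists, genes called lower on both 335 against 14.9, and 11 were called in opposite directions. Both contrasts take each gene's spread from 1 fit, so a gene with a small spread is more easily called in both. The counts for independent lists may therefore be too low. The average contrast over both backgrounds called 8805 genes, 5537 higher and 3268 lower (62.9% higher, against 72.1% after rescaling to TPM, 46.7% with median-of-ratios scaling and 48.5% with quantile normalization). This count was 4399 without CORT_white_1, 5003 without CORT_white_3, 5393 without CORT_black_2 and 5601 without CORT_black_1. In the average contrast GP2 (TRINITY_DN41119_c0_g1) rose by 5.58 ± 0.14 (adjusted p = 4.1e-09), P450 2G1 by 5.14 ± 0.14, OLFM4 by 4.50 ± 0.21, KLF9 by 2.88 ± 0.21 and TSC22D3 by 0.74 ± 0.13 (adjusted p = 0.0034). FBXO32, a ubiquitin ligase of muscle atrophy, rose by 1.94 ± 0.32, and ALPL (TRINITY_DN51561_c6_g3), an alkaline phosphatase, fell by −3.29 ± 0.22. An assembled gene of MUC5AC other than the one that fell on black (TRINITY_DN51265_c1_g1) rose by 4.13 ± 0.88 (adjusted p = 0.011), a call that ended without CORT_white_3 (adjusted p = 0.057; 0.0034 to 0.057 over all alternatives). Glucocorticoid-induced genes had 16 rises and 0 falls (17 and 1 adjusted over the list alone; adjusted p = 5.7e-06; adjusted p = 0.207 with an estimated correlation), and muscle genes 21 falls and 1 rise (22 and 3 adjusted over the list alone; adjusted p = 7e-18; adjusted p = 0.207 with an estimated correlation). Interferon response genes had 9 rises and 0 falls among 16 (14 and 0 adjusted over the list alone; median 1.13, adjusted p = 0.0042; adjusted p = 0.959 with an estimated correlation).

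The third comparison set a white against a black background without corticosterone. The precursor of the pigment-dispersing hormone α-MSH, POMC (TRINITY_DN33973_c0_g1), was at 27.3 ± 5.24 FPKM on black and 1.76 ± 2.20 on white (SD, n = 3 and 3), with every black library (21.6, 28.6 and 31.8) above every white one (0, 1.04 and 4.22). With 3 libraries against 3, chance separates the groups fully, in either direction, for 10% of genes. The log2 change of POMC, −3.67 ± 0.60, had an adjusted p of 0.098 over all genes and of 3.8e-04 adjusted over the list alone, that of background-colour hormones and receptors. Across the alternatives the adjusted p over all genes ran from 0.028 with the replicate block to 0.51 with a pseudocount of 0.01, and it was 0.044 without control_white_3. Other pituitary hormone genes had lower values on white that passed adjusted over the list alone and not over all genes: growth hormone GH1 (−2.71 ± 0.60, adjusted p = 0.28, list alone 0.0024), prolactin PRL (−0.97 ± 0.18, 0.14, list alone 5.9e-04) and the glycoprotein hormone subunit CGA (−1.26 ± 0.22, 0.13, list alone 5.9e-04). GH1, PRL and CGA stand outside the rules for the background comparisons and were chosen after their values were seen. Over all genes PRL passed with no filter (adjusted p = 0.041; 0.041 to 0.64 over all alternatives) and CGA with array weights (0.041; 0.041 to 0.55), and GH1 passed in none (0.054 to 0.64). The list of appetite and pituitary hormones had a median of −0.33 (adjusted p = 2.5e-07; adjusted p = 0.297 with an estimated correlation), with 0 of 12 members called and 4 lower adjusted over the list alone; 7 of the 12 were lowest in control_white_1. This median was −0.06 without control_white_1, −0.60 without control_white_2, −0.81 without control_white_3, −0.15 without control_black_2 and −0.61 without control_black_3. Background-colour hormones and receptors had 0 of 7 called and 2 lower adjusted over the list alone (median −0.15, adjusted p = 5.6e-04; adjusted p = 0.297 with an estimated correlation), and their median ran from −0.33 without control_black_3 to 0.09 without control_black_2, with −0.29 without control_black_1, −0.03 without control_white_1 and −0.32 without control_white_3.

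No gene of melanin synthesis passed the test between backgrounds without corticosterone. Tyrosinase TYR, the first enzyme of the pathway, changed by −0.16 ± 0.37 (adjusted p = 0.94), PMEL by −0.47 ± 0.24 (adjusted p = 0.65), DCT by −0.38 ± 0.28 (adjusted p = 0.75), TYRP1 by 0.15 ± 0.22 (adjusted p = 0.89) and their regulator MITF by 0.45 ± 0.25 (adjusted p = 0.67). TYR took the other sign with array weights (0.26) and without control_white_1 (0.13) or control_black_2 (0.10), and TYRP1 without control_black_3 (−0.03) and, by under 0.01, without control_white_2. In the melanin list 0 of 23 members were called by limma, also adjusted over the list alone, with a median of 0.00 and an adjusted p of 1. MC1R, PMCH and ASIP were not measured.

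Secreted liver proteins were higher on white as a list (median 0.77, and 0.40 without control_black_2; adjusted p = 1.5e-12; adjusted p = 0.569 with an estimated correlation), with 0 of 34 called over all genes and 10 higher adjusted over the list alone. Among these, the protease inhibitor A2M, chosen after its values were seen, changed by 1.76 ± 0.36 (adjusted p = 0.22, list alone 0.013). Complement and acute-phase genes had a median of 0.73, or 0.36 without control_black_2 (adjusted p = 4.8e-08; adjusted p = 0.569 with an estimated correlation), with 0 of 28 called and 4 higher adjusted over the list alone. Amino acid catabolism had a median of 0.51, or 0.28 without control_white_1 (adjusted p = 3e-06; adjusted p = 0.569 with an estimated correlation), with 0 of 26 called either way. Muscle genes had a median of −0.35, or −0.23 without control_black_2 (adjusted p = 3.3e-11; adjusted p = 0.342 with an estimated correlation), with 0 of 35 called. Digestive genes were higher on white as a list (median 1.81, or 0.57 without control_white_1; adjusted p = 5.3e-05; adjusted p = 0.569 with an estimated correlation), with 0 of 26 called and 7 higher and 1 lower adjusted over the list alone. Photoreceptor genes (median −0.98, adjusted p = 3e-09) and lens genes (−1.31, adjusted p = 7e-06) were lower as lists, and both calls ended without control_white_1, with medians of −0.01 and 0.13. With an estimated correlation both had an adjusted p = 0.569. In this comparison camera called 20 of the 39 lists with the preset correlation, and fry called 0. The photoreceptor median was −1.62 without control_white_3, and the lens median was −0.78 without control_black_1, −2.07 without control_white_2 and −1.996 without control_white_3.

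Single genes called between backgrounds without corticosterone numbered 29, 6 higher and 23 lower on white, with 6590 at an unadjusted p under 0.05. The count was 8 without control_black_1, 10 without control_white_2, 16 without control_white_3, 18 without control_black_3, 54 without control_black_2 and 45 without control_white_1. Only 4 had a name. Ornithine decarboxylase (DCOR, TRINITY_DN37599_c2_g2), the first enzyme of polyamine synthesis, rose from 0.620 ± 0.174 to 3.24 ± 0.380 FPKM (1.39 ± 0.17, adjusted p = 0.016), a call that ended without control_black_1 (adjusted p = 0.079), control_black_3 (0.084), control_white_2 (0.13) or control_white_3 (0.063), and with a range of 0.0059 to 0.20 over all alternatives; with a pseudocount of 0.01 its change was 2.40. STYL1 fell from 11.9 ± 2.28 to 1.02 ± 0.242 FPKM (−2.66 ± 0.28, adjusted p = 0.0065), a call that ended without control_black_1 (adjusted p = 0.061; 0.0020 to 0.061 over all alternatives). The others, named for CYTB and EPDR1, were listed at 0 in each white library, and their best hits over all proteins lay in a rotifer and in a lancelet. The CYTB call ended without control_black_1 (adjusted p = 0.27), control_black_3 (0.21), any one control_white library (0.075 to 0.21) or any one CORT_black library (0.053 to 0.094). The EPDR1 call ended without control_black_1 (adjusted p = 0.085), control_black_3 (0.057), control_white_2 (0.082) or control_white_3 (0.054). Of the rest, 1 (TRINITY_DN18262_c0_g1, chosen after its values were seen) had a hit to cytochrome c oxidase subunit 1 outside the chordates. Its best hit over all proteins also lay in a rotifer, and it was at 13.7 ± 8.32 FPKM in control_black and 0 in control_white. The other 24 had no Swiss-Prot hit. One of these, chosen after its values were seen (TRINITY_DN36274_c5_g1), was at 7.72 ± 0.789 FPKM in control_black and 0.0671 ± 0.0763 in control_white (−3.03 ± 0.22, adjusted p = 9e-04), and at 5.87 ± 1.91 and 4.72 ± 0.597 in CORT_black and CORT_white. TRINITY_DN42322_c4_g6, chosen likewise, had means of 7.19, 0.210, 5.83 and 4.84 FPKM in the same order. Calls with so like a profile need not be separate results.

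**Figure D4:**
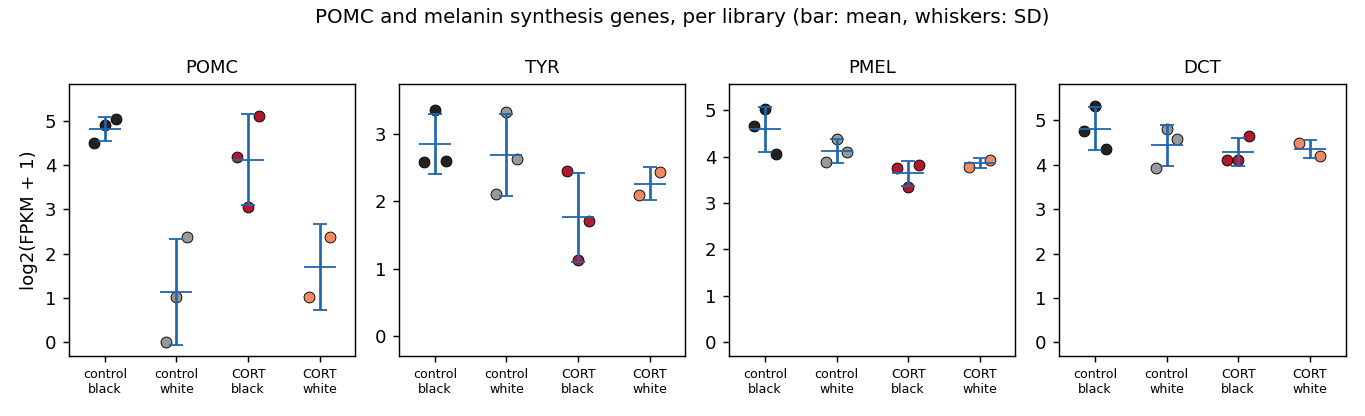
Values of log2(FPKM + 1) per library (points) for POMC, TYR, PMEL and DCT in the 4 groups, with the group mean (bar) and SD (whiskers; n = 3, 3, 3 and 2). POMC is lower in each white library than in each black one, and TYR, PMEL and DCT overlap between backgrounds.

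With corticosterone, white against black gave 3 calls, all lower on white and all without a name, with 3197 genes at an unadjusted p under 0.05. The count was 24 without control_white_1 and at most 1 without any other single library. POMC was at 19.3 ± 13.2 FPKM in CORT_black and 2.62 ± 2.24 in CORT_white (SD, n = 3 and 2), a log2 change of −2.41 ± 0.67 (adjusted p = 0.986 over all genes, 0.026 adjusted over the list alone). TYR changed by 0.50 ± 0.41, TYRP1 by 0.72 ± 0.24 and PMEL by 0.22 ± 0.27, each with an adjusted p of 1. Muscle genes were higher on white as a list (median 0.36, adjusted p = 6.4e-10; adjusted p = 0.677 with an estimated correlation), with 0 of 35 called. Digestive genes were lower on white as a list (median −2.07, adjusted p = 0.029; adjusted p = 0.914 with an estimated correlation), with 0 of 26 called, also adjusted over the list alone. This call ended without control_black_1 (adjusted p = 0.055), control_black_2 (0.092), control_black_3 (0.092), CORT_black_3 (0.11) or CORT_white_1 (0.34), and without control_white_1 the adjusted p was 3.1e-10 with 2 members lower.

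Averaged over both exposures, POMC changed by −3.04 ± 0.45 (adjusted p = 0.143 over all genes, 1.5e-04 adjusted over the list alone). Its adjusted p over all genes ran from 0.042 with array weights to 0.79 with a pseudocount of 0.01. The average background contrast called 8 genes, 2 higher and 6 lower, none with a name, against 2 higher and 3 lower with quantile normalization, with 3863 at an unadjusted p under 0.05. Without CORT_black_3 the count was 30 and without control_white_1 it was 17, and without any other single library it was at most 1.

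The interaction asked whether the corticosterone effect differed between backgrounds, and 12 genes passed, 3 higher and 9 lower, with 5514 at an unadjusted p under 0.05. None had a Swiss-Prot hit. With TPM the split was 1 higher and 9 lower, and median-of-ratios scaling gave 0 calls. The count was 0 without control_black_1, control_black_3 or CORT_white_3, 1 without CORT_white_1 or control_white_3, 2 without CORT_black_1, 6 without control_white_2, 7 without CORT_black_2, 8 without CORT_black_3, 18 without control_black_2 and 26 without control_white_1. All 9 lower genes had group means that were higher on white than on black without corticosterone and lower on white with it. For TRINITY_DN46057_c2_g1, chosen after its values were seen, the means were 33.5 ± 1.59, 65.3 ± 10.7, 78.7 ± 9.73 and 25.9 ± 1.37 FPKM in control_black, control_white, CORT_black and CORT_white (interaction −2.49 ± 0.23, adjusted p = 0.014). TRINITY_DN41295_c7_g1, chosen likewise, had means of 30.8, 65.0, 81.2 and 28.4 FPKM in the same order. Such near-proportional genes may be pieces of 1 gene or vary together, so the 12 calls need not be separate results.

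Named genes of the corticosterone comparisons did not pass this test. For KLF9 the interaction was 0.34 ± 0.41 (adjusted p = 0.91), for TSC22D3 0.32 ± 0.25 (adjusted p = 0.84), for TTN 0.77 ± 0.27 (adjusted p = 0.66) and for MYH8 1.18 ± 0.38 (adjusted p = 0.62). TTN and MYH8 stand outside the rules for this comparison and were chosen after their values were seen. As lists, muscle genes (median 0.77, adjusted p = 9.1e-17; adjusted p = 0.402 with an estimated correlation) and digestive genes (median −4.04, adjusted p = 1.1e-04; adjusted p = 0.500 with an estimated correlation) differed between backgrounds. In both lists 0 members were called by limma, and adjusted over the list alone 14 of the 26 digestive genes were lower. The digestive genes were high in control_white_1, and without that library their list was still called (median −2.75, adjusted p = 4.6e-08), with 2 members lower. Glucocorticoid-induced genes had an interaction median of −0.12 (adjusted p = 0.82).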

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

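The tests of missing head tissue, of a few abundant genes, of sequencing depth and of scaling over all genes were chosen only after the results they bear on were seen. The interaction of corticosterone and background stood out because the effects on the 2 backgrounds differed by a test of the difference itself. In limma 12 genes passed, 3 with a higher and 9 with a lower response on white, and none had a Swiss-Prot hit. Several of these had near-proportional group means, and an assembly can split a gene, so the 12 need not be separate results. The count was 0 without control_black_1, control_black_3 or CORT_white_3 (5294 to 5613 genes at an unadjusted p under 0.05), 1 without CORT_white_1 or control_white_3, 2 without CORT_black_1, 6 without control_white_2, 7 without CORT_black_2, 18 without control_black_2 and 26 without control_white_1.

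Other splits of the libraries were tested for some counts of called genes, that of the interaction not among them. For the average corticosterone contrast 100 of the 200 possible splits within backgrounds were drawn, and 2 of them, the real one included, called as many genes. That share is under 0.05, so chance is argued against but not excluded. Permuting libraries takes them as independent, which the labels do not state. The real split called 8805 genes and the highest of the others 9214. That other split exchanged exposed and unexposed libraries except control_white_1 and is thus nearly the mirror image of the real one. The real count was 4399 without CORT_white_1, 5003 without CORT_white_3, 5393 without CORT_black_2 and 5601 without CORT_black_1. For the average background contrast the real split called 8 genes and 7 of 100 drawn splits called as many, with a highest other count of 70, so chance cannot be excluded. Another draw of as many splits gave a share under 0.05, so this share lies close to that threshold. For corticosterone on black the 10 splits of 6 libraries are too few for a share under 0.05; 1 of them, the real one, called 7662 genes, and the highest other called 0 in limma, with 2226 at an unadjusted p under 0.05. For the background effect without corticosterone the 10 splits are too few as well; 2 of them called as many genes as the real split, with 29 in the real split and 325 in the highest other.

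Both background counts were exceeded several times over by a split that put control_white_1 with control_black_1 and control_black_2, which points to a structure of the samples other than background. Of the 325 genes of that split, 160 had their best protein hit in Sphaeroforma, a genus of unicellular relatives of animals, against 0 of the 29 genes of the real split.

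Library control_white_1 stood apart from the other 10 libraries. A mislabelled exposed sample is argued against: over the genes called on black, its deviation from the mean of the other control_white libraries had a slope of 0.185 on the corticosterone effect, against 0.595 and 0.608 for the CORT_white libraries, measured from the same mean. The other control_white libraries were each measured from the other, which gave a single difference, 0.131 or −0.131 by direction. A few genes taking most of the FPKM are argued against too, since the 100 highest genes of control_white_1 held 37.5%, within the range of 29.8% to 37.7% over the libraries. RNA of head tissue missing from the sample stays open as a hypothesis: the library was the lowest of the 11 in 87.3% of the measured genes of lens (16 of 16), photoreceptors (24 of 26) and neurons (15 of 21), against 21.1% in all other lists, although 65 of 75 cytosolic ribosomal protein genes were lowest there as well. The design names no biological difference within a group, and no biological explanation was tested.

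The 2474 assembled genes with a best protein hit in Sphaeroforma summed to 3602, 2427 and 818 FPKM in control_black_1 to control_black_3, 5950, 489 and 898 in control_white_1 to control_white_3, 921, 780 and 902 in CORT_black, and 279 and 610 in CORT_white. A difference in depth is argued against, because relative depths lay within 1.06-fold of each other. RNA of another organism in the tadpoles or their gut may account for the pattern: across the 11 libraries, the only such relation computed, the sum of ribosomal protein genes with such a hit followed that of all other such genes with a Spearman rho of 0.9 (permutation p = 4e-04) and a Pearson r of 0.993 (permutation p = 1e-05, the smallest these permutations can give), and r was 0.982 without control_white_1 and control_black_1, the 2 libraries farthest from the median. Those ribosomal protein genes spanned a 20.05-fold range, against 1.37-fold for frog ribosomal proteins. An effect of exposure stays open, with a log2 difference of −1.34 between exposed and unexposed libraries (exact permutation p = 0.0996, two-sided, 462 splits), and of 501 such genes tested 6 were called on black and 26 in the average corticosterone contrast, all lower, a smaller share than the 7662 and 8805 of all 80014 genes tested.

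More genes rose than fell with corticosterone, 62.9% of the calls in the average contrast. The share was 72.1% after rescaling to TPM and 46.7% with median-of-ratios scaling, but the latter centres the change of all genes (median log2 0.0050) and so sets this balance. For that reason scaling and a real excess cannot be told apart over all assembled genes. Among called symbols 81.8% rose, and 69.1% still did with median-of-ratios scaling, against 39.4% of the called genes with no Swiss-Prot hit. Median-of-ratios scaling thus did not remove the excess among named symbols. It left them at a median log2 change of 0.096, so they rose relative to the other assembled genes. No scaling centred on named genes was tried, so scaling and a real excess cannot be told apart for them either. A response of named genes to corticosterone that goes mainly upward stays open as a hypothesis.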

How the results depend on the processing

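The tests restricted to genes with a chordate hit, and the tests of lists with each library left out, were chosen only after the data were seen. For the 344 results on named genes, 7081 values under alternatives kept direction and side of the threshold, 899 kept the direction and lost the call, 20 gained a call and 29 changed sign, 0 of these on a called gene. The 29 include a value of PRL that came to 0. For the 114 list calls these numbers were 1199 kept, 383 lost and 14 turned. Counts of called genes stayed within 1.5 times in 79 cases and moved further in 86. A minimum fold lowers a count by construction and a stricter filter leaves fewer genes to call. Leaving out a library of neither group compared acts on a count only through the shared spread and the genes tested. For the remaining changes, other left-out libraries included, the cause was not tested. The absolute depth is unknown, so the lowest level that can be told from 0 is not known either, and relative depths of 0.965 to 1.03 leave little room for differences in precision from depth.

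With a mean FPKM of 5 or more as the filter, 4364 genes were called on black, 5040 in the average corticosterone contrast, 7 between backgrounds without corticosterone, 1 with it and 0 on average (852 at an unadjusted p under 0.05 in limma), and r between the corticosterone effects was 0.660. With no filter, the background contrasts called 50 genes without and 5 with corticosterone. Genes with a chordate hit alone gave 4138 on black, 586 on white, 4365 on average, 3 between backgrounds without corticosterone, and 0 with it, on average and for the interaction (791, 819 and 1527 at an unadjusted p under 0.05). A minimum of 1 on the log2 scale left 3866 on black and 2479 on average. Array weights, which gave control_white_1 the lowest weight (0.275), called 13886 on black, 2916 on white, 14966 on average, 108, 14 and 28 between backgrounds (without, with, average) and 20 for the interaction, and TYR without corticosterone changed to 0.26. Fits of the 2 groups alone called 78 on white, 19 between backgrounds without corticosterone and 0 with it (5181 at an unadjusted p under 0.05).

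A pseudocount of 0.1 gave 0 calls between backgrounds with corticosterone (3041 at an unadjusted p under 0.05), 21 for the interaction, an r of 0.469, and interaction values of 0.040 for ZBTB16 and 0.031 for THRB; with 0.01 these values were 0.42 and 0.046. Rescaling to TPM gave 7 calls between backgrounds with corticosterone and robust moderation 6. Median-of-ratios scaling gave 0 calls there and 0 for the interaction (2963 and 5617 at an unadjusted p under 0.05), NR3C1 on white at −0.017 and the THRB interaction at 0.0065. Quantile normalization left 5 calls in the average background contrast.

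Replicate numbers did not pair the samples: deviations of 15 same-numbered pairs correlated between −0.159 and 0.160, with 1 pair over 0.1, those of 30 other pairs between −0.169 and 0.218, and 5 of 11 libraries correlated best with their own number. The replicate block called 6790 genes on black, 1153 on white, 7815 on average, 22 between backgrounds without corticosterone, 0 with it and 0 on average (3224 and 3763 at an unadjusted p under 0.05) and 5 for the interaction, where THRB was at 0.011.

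For the lists, an estimated correlation gave 0 calls in all 7 comparisons. Fry called 10 lists on black and 3 on white, and 0 in each background contrast and for the interaction. On black fry gave the other direction for antioxidant defence (median −0.10), ribosomal proteins (0.063), fatty acid oxidation (−0.021), photoreceptors (−0.026) and the proteasome list (0.031), and with all assembled genes of a symbol ribosomal proteins turned between backgrounds with corticosterone (median 0.050).

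With each library left out in turn, the counts ran from 2829 (CORT_black_2) to 11649 (control_white_1) on black, from 429 (CORT_white_1) to 2153 (control_white_1) on white and from 4399 (CORT_white_1) to 12682 (control_white_1) on average. Between backgrounds they ran from 8 (control_black_1) to 54 (control_black_2) without corticosterone, from 0 to 24 (control_white_1) with it and from 0 to 30 (CORT_black_3) on average, and for the interaction from 0 to 26 (control_white_1). The counts of 0 came with 2264 to 3372, 2728 to 4980 and 5294 to 5613 genes at an unadjusted p under 0.05. With 1 exposed white library left, that library is assumed to vary like the other groups. The called lists between backgrounds without corticosterone numbered 13 (control_white_1) to 22 (control_white_3), and r ran from 0.436 (control_white_3) to 0.603 (control_white_1).

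Genes that were not called and whose sign depended on a library were, without corticosterone between backgrounds, TYR (−0.48 to 0.13) and TYRP1 (−0.032 to 0.36), and with it DCT (−0.082 to 0.24), MITF (−0.23 to 0.018) and GH1 (−0.77 to 0.54). PRL with corticosterone ran from −0.054 to 0, so it reached 0 and did not take the other sign. On white it was NR3C1 (−0.069 to 0.26), and for the interaction PER1 (−0.10 to 0.30), ZBTB16 (−0.29 to 0.0036), PCK1 (−0.063 to 0.95) and THRB (−0.11 to 0.10). For some lists the direction given by camera turned without a library, whether or not the median changed sign, and the ranges here are those of the medians. On white it turned for digestive genes (−1.19 to 0.59) and photoreceptors (0.064 to 2.01) without control_white_1. Without control_black_3 it turned for the proteasome list on black (−0.040 to 0.18, with 0.18 in that setting and 0.031 with all libraries) and between backgrounds without corticosterone (−0.11 to 0.10). Without control_white_1 ribosomal proteins (−0.12 to 0.11) and growth hormone signalling (0.12 to 0.37) turned between backgrounds without corticosterone, as did photoreceptors on average (−0.76 to 0.0075), and without CORT_white_1 cell cycle genes with corticosterone (−0.52 to 0.022).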

Other observations

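Named genes of the first paragraphs follow the rules set before the data were examined. The lists were also written before then, but no rule set which of them are described. The sums over genes of rotifers and ciliates were chosen only after the data were seen. On black, corticosterone moved genes of oxidative defence both ways. NFE2L2, a main regulator of antioxidant genes, rose from 43.6 ± 6.18 to 94.9 ± 3.75 FPKM (SD, n = 3 and 3; log2 change 1.11 ± 0.16, SE, limma adjusted p = 0.0017), and heme oxygenase HMOX1 from 4.97 ± 2.63 to 18.4 ± 1.34 FPKM (1.78 ± 0.29, adjusted p = 0.0038). NQO1, known as a target of NFE2L2, fell from 66.2 ± 14.4 to 30.1 ± 6.04 FPKM (−1.11 ± 0.21, adjusted p = 0.0080). In the antioxidant list 3 of 23 genes rose and 4 fell, also adjusted over the list alone. The list was called downward relative to the other named symbols (median −0.10, camera adjusted p = 0.028, and 0.934 with an estimated correlation). Its mean was 0.06, so mean and test differ in sign. This call ended without control_black_3 (median 0.05, adjusted p = 0.14), CORT_black_1 (−0.05, 0.069) or CORT_black_2 (0.01, 0.064), and the median was 0.09 without control_black_1, −0.04 without control_black_2 and 0.04 without CORT_black_3. Among innate immune genes, BPI, a protein that binds and kills bacteria, rose on black from 20.4 ± 4.06 to 69.5 ± 5.12 FPKM (1.74 ± 0.17, adjusted p = 1.4e-04), and C-reactive protein (CRP) by 1.93 ± 0.38 (adjusted p = 0.0096). The list of complement and innate immunity had 5 rises and 0 falls among 28 genes (7 and 0 adjusted over the list alone) and was not called (median 0.60, adjusted p = 0.207).

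Averaged over both backgrounds, 8 of 20 enzymes of glycolysis rose and 1 fell (9 and 1 adjusted over the list alone; median 0.25), and the list was not called (adjusted p = 0.612). The muscle form of enolase, ENO3, rose by 1.58 ± 0.23 (adjusted p = 0.0012) and aldolase ALDOA by 1.18 ± 0.19 (adjusted p = 0.0022). GAPDH, often taken as a reference gene in PCR, stood at 1899 ± 277 and 1707 ± 155 FPKM in control_black and control_white and at 3216 ± 345 and 3791 ± 509 in CORT_black and CORT_white (0.96 ± 0.11, adjusted p = 2.8e-04), and it was called upward under each scaling tried, with 0.84 at the lowest, by median-of-ratios scaling. Enzymes of the intestinal brush border went both ways: maltase-glucoamylase MGAM fell by −1.20 ± 0.14 (adjusted p = 2.4e-04) and aminopeptidase ANPEP by −1.34 ± 0.16 (adjusted p = 3.8e-04), while the protease subunit MEP1A rose by 1.43 ± 0.20 (adjusted p = 0.0010). Of the 26 digestive genes, villin and other genes that are not enzymes among them, 6 rose and 6 fell (12 and 6 adjusted over the list alone). That list was not called (adjusted p = 0.116, or 0.041 without control_white_3), with a median of 1.45 and a downward direction of the test. In the pigment cell list, the endothelin receptor EDNRB, which acts in neural crest cells, rose on black from 1.90 ± 0.396 to 7.96 ± 0.532 FPKM (1.63 ± 0.25, adjusted p = 0.0025); 5 of 23 members rose there and 3 fell (9 and 4 adjusted over the list alone), and the median of 0.16 and the direction of the test, downward, differ in sign (adjusted p = 0.447). Prolactin (PRL) fell on black from 1.06 ± 0.0544 to 0.0261 ± 0.0453 FPKM (−1.01 ± 0.18, adjusted p = 0.0057), a call that ended with a pseudocount of 0.01 (−5.70, adjusted p = 0.13) and held in all other alternatives that tested it.

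Assembled genes with a best protein hit in a genus of rotifers (114 genes) summed to 225, 40.5 and 146 FPKM in control_black_1 to control_black_3 and to 77.1, 67.6 and 4.75 FPKM in CORT_black_1 to CORT_black_3. On white their sums were 4.27, 5.57 and 4.02 FPKM without corticosterone and 6.21 and 4.61 FPKM with it. For genes with a hit in ciliates (319 genes) the highest sum was 804 FPKM in control_white_1 and the lowest 113 FPKM in CORT_white_3.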
